A study of Danio rerio with 4 samples.

How the data were processed

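Total RNA from whole zebrafish embryos was labelled with Cy3 and hybridised to 4 one-colour Agilent Whole Zebrafish Genome arrays, per the labels' protocols. The arrays fall into 2 groups by their titles: 2 from embryos injected with the T1 morpholino and 2 from embryos injected with the standard control morpholino. Per the series' design text the 2 arrays of a group are biological replicates. The labels' protocols also name the morpholinos T2 and S1, which were not analysed here. All 4 arrays lay on 1 slide with 1 scan, so neither could act as a batch.

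The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 10.5.1.1, per the file headers. In them the processed signal is the spot intensity after background subtraction and detrending, with surrogate values for the dimmest spots, and it is not scaled between arrays. The authors also deposited a table of intensity values divided by the median of each array, per its header. Its control columns had a median of 1 and equalled the processed signal divided by its median over the 43803 non-control spots, with an SD of the log2 ratio of at most 5.29e-06. Another 2 columns of that table carry a name that the labels do not explain and were not used, so no fit was made on that table. Its scaling is the same operation as the median scaling that was tried.

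The values analysed were log2 processed signals minus the 75th percentile of each array. Control spots were left out, as were spots flagged as non-uniformity or population outliers, between 11 and 47 per array, and spots of one probe were averaged. This left 43603 probes. The probes well above background numbered 28016 and 29135 on the T1 arrays and 29444 and 28906 on the control arrays, and 0 spots were saturated. The median processed signal ran from 46.4 to 49.7 and the 75th percentile from 501 to 593. The number of arrays limits the precision. Probes well above background on both arrays of at least 1 group were tested, 28641 in all.

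Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend, two-sided, and p-values were adjusted by the Benjamini-Hochberg method. An adjusted p under 0.05 was called. For each gene symbol the tested probe with the highest mean log2 signal over the 4 arrays stood for the gene, and the p-values of these 13316 genes were adjusted among themselves. Values printed with ± are log2 fold changes, T1 minus control, with the standard error of that fit and 2 arrays per group. Unless stated otherwise, each adjusted p of a gene comes from this fit. Where a gene was not well above background on any array of a group only a bound is given. The bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background.

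Probe names came from accessions, symbols or synonyms matched to a RefSeq gene table (17329, 1603 and 1148 probes) and otherwise from the files (23523 probes). Of the 43603 probes, 24862 carried a clone, locus or accession name. Probe positions are those in the scanner files, on the danRer5 (Zv7) build. No annotation of that build was used, so positions within exons or untranslated regions are not given.

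Before the data were examined, 33 gene lists were fixed, with the tests, the alternatives and the rule for naming genes. Lists with at least 5 measured genes, 32 of them, were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With an estimated correlation camera takes its degrees of freedom from the 4 arrays, so that setting has little power here. Another 3 lists were added after the data were seen and appear only in the closing observations. The genes named were every beta-defensin probe, the 10 genes with the largest change in each direction among those past the threshold whose T1 arrays both lay beyond both control arrays, up to 4 members past the threshold from each list that was called or had such a member, and further genes fixed by name, among them mdm2, cdkn1a, ccng1, myod1, myf5 and myog. Not every gene that the rule takes is given in the text or drawn. Clone and locus names were left out of the ranking, and genes with only a bound were given apart from it. cdkn1a was not analysed here. Any other gene named was chosen after its values were seen.

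The fit was tested on simulated data with the probe means of these arrays and variances drawn from the fitted prior. In 5 runs of 28641 probes with 200 changed probes, 2.6% of the changes of 1 on the log2 scale and 46.2% of the changes of 2 were recovered, with a mean of 1.8 false calls per run. A simulated list of 20 genes raised by 1 was called in 5 of 5 runs, and 0 of 150 random lists were called. The simulated probes varied independently of each other. These runs are therefore no check of the list test where members are correlated. Among the called lists this holds for the ribosomal and gastrula-stage lists, with estimated correlations of 0.436 and 0.269. The alternatives tried were normexp background correction with an offset of 50, median, quantile and no scaling, no filter and a filter on all 4 arrays, leaving out each array, the replicate number as a block, eBayes without the trend or with robust estimation, an adjusted p under 0.10, a minimum of 2-fold, and the mean of all probes of a gene. When an array was left out, the group with a single array was assumed to vary like the other. Intervals of list medians are 95% bootstrap intervals over member genes from 2000 draws. Smooth trends were fitted with mgcv 1.9.3, and figures were drawn with matplotlib 3.10.9.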

Results

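Gene expression was measured in whole zebrafish embryos of the AB strain at 12.5 h post fertilization, an early somite stage. Embryos had been injected at the 1-cell stage with about 1 nl of a morpholino, an antisense oligonucleotide that blocks the translation or splicing of its target RNA. The T1 morpholino was directed at defbl1, a gene for a beta-defensin, a family of small antimicrobial peptides, and was used at 62.5 µM. Control embryos received a standard control morpholino, whose concentration is not given in the sources used here. Each group had 2 biological replicates, each on a one-colour array. Between 64.3% and 67.5% of the 43603 probes were well above background on an array. The log2 differences between the replicate arrays had an SD of 0.49 in the T1 group and 0.40 in the control group. The comparison asked which transcripts differed in embryos injected with the defbl1 morpholino.

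The targeted transcript came first. The defbl1 probe, on chromosome 21 at 10561886 to 10561945 of danRer5, was not well above background on any array. Its processed signals were 2.2 and 5.34 in T1 embryos and 3.26 and 3.31 in control embryos, against a lowest signal among probes well above background of 8.07 to 10.7 per array. The probes of defbl2, on chromosome 21 at 10473607 to 10473666, and of defbl3, on chromosome 15 at 5524698 to 5524757, were likewise not well above background on any array. None of these 3 probes was tested, and no fold is given. The T1 sequence GGGCTTCATGTTGGATTCTTCAGAT is complementary to ATCTGAAGAATCCAACATGAAGCCC, which holds a start codon triplet at bases 17 to 19. A morpholino over a start codon need not change the level of its transcript, so these signals are no check of the knockdown.

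Genes with a large rise in T1 embryos included targets of p53, the transcription factor that responds to DNA damage and other cell stress. gadd45aa, a growth arrest and DNA damage gene on chromosome 2 (probe at 7423445 to 7423504), rose by 5.52 ± 0.22 on the log2 scale (SE, n = 2 per group), 45.8-fold. bbc3, which encodes the pro-apoptotic protein Puma, rose by 4.29 ± 0.19, or 19.6-fold, and phlda3, an inhibitor of Akt signalling, rose 17.1-fold, with an SE of 0.17 on the log2 scale. foxo3b, a forkhead transcription factor, rose by 3.62 ± 0.16 and casp8, an initiator caspase, by 3.40 ± 0.17. mdm2, which encodes the ligase that degrades p53, rose by 2.67 ± 0.17 and ccng1, a cyclin G gene, by 1.29 ± 0.12.

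Of the 20 measured genes in the p53 target list, 10 rose, none fell and 10 did not pass the test. Adjusted over the list alone, 12 were higher and 1 was lower. The adjusted p from limma was 0.000846 for gadd45aa, bbc3, phlda3 and foxo3b, 0.00121 for casp8, 0.00347 for mdm2 and 0.0151 for ccng1. Among the other members past the threshold was sesn3, at 2.17 ± 0.15. sesn1, at 1.58 ± 0.24 (adjusted p = 0.0549), and baxa, at 0.93 ± 0.14 (adjusted p = 0.0579), did not pass, and plk2b stood at -1.22 ± 0.30 (adjusted p = 0.175). The list had a median of 1.21 and a mean of 1.65, with camera giving an adjusted p = 1.74e-13, and adjusted p = 0.461 with an estimated correlation. Genes past the threshold upward numbered 10 of the 20 in the list against 52 of the other 13296 genes, or 0.391% (Fisher's exact test across genes, which are not independent replicates, p = 3.98e-19). Both mdm2 probes and all 3 ccng1 probes passed. Without control replicate 1 the members that passed numbered 8, and ccng1 was not among them (adjusted p = 0.0571). The apoptosis machinery list did not hold bbc3 or casp8. None of its 17 measured genes passed, and its median was 0.14 (camera adjusted p = 0.444), but -0.07 without T1 replicate 1 and 0.02 without control replicate 2.

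**Figure D1:**
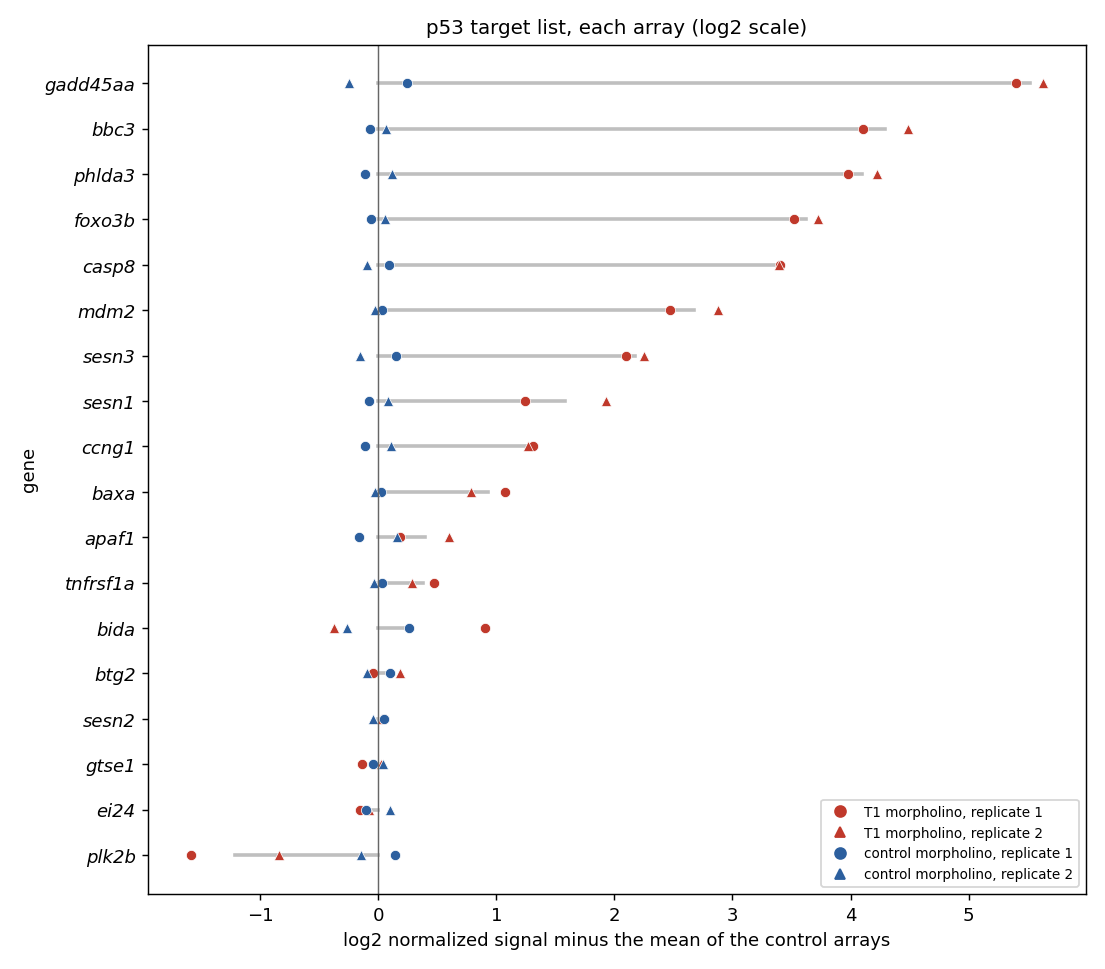
Each point is the log2 normalized signal of a member of the p53 target list on 1 array minus the mean of the control arrays, in red for T1 and blue for control embryos, with circles for replicate 1 and triangles for replicate 2 and a grey line to the T1 mean. Both T1 arrays lie beyond both control arrays for each gene drawn that passed the threshold, from gadd45aa at 5.52 to ccng1 at 1.29, and not every list member is drawn.

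Other genes with a large rise were not on the p53 list. fosab, an immediate early gene of the AP-1 transcription factor, rose by 4.39 ± 0.20 (adjusted p = 0.000846), and all 5 of its probes passed, at 4.39 to 5.42. rspo1, a secreted activator of Wnt signalling, rose by 3.89 ± 0.23 (adjusted p = 0.003), and slc34a2b, a sodium-phosphate cotransporter, by 3.62 ± 0.29 (adjusted p = 0.007), with 1 of its 2 probes past the threshold over all probes. metrnlb rose by 3.20 ± 0.23 (adjusted p = 0.0052). The chemokine receptor gene cxcr3.1 rose by 3.80 ± 0.44 (adjusted p = 0.0268) and was well above background on 1 of the 2 control arrays. Its call was lost without the filter on dim probes (adjusted p = 0.0512) and without the variance trend (0.0778). ifit8, of an interferon-induced family, was not well above background in control embryos and was at least 13-fold higher in T1 embryos (adjusted p = 0.00393). With normexp background correction, under which the stated bound does not hold, ifit8 stood at 1.31, cxcr3.1 at 1.2, metrnlb at 1.77, slc34a2b at 2.00, rspo1 at 3.01 and gadd45aa at 4.75, all past the threshold. ifit8 was the only gene past the threshold among 16 in the interferon and antiviral list, also when adjusted over the list alone (camera adjusted p = 0.761), and the list had a median of -0.02 but a mean of 0.26. fosab stood alone in the same way among 27 genes of the inflammation and antimicrobial list (camera adjusted p = 0.195), which was called without T1 replicate 1 (adjusted p = 0.00511).

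The genes that fell most included transcription factors of the developing brain, sense organs and ionocytes. en2b, a gene of the midbrain-hindbrain boundary on chromosome 2 (probe at 24413530 to 24413589), fell by 2.65 ± 0.32 on the log2 scale (6.27-fold lower, adjusted p = 0.03). hmx4 fell by 2.35 ± 0.32 and hmx1 by 2.17 ± 0.26, both homeobox genes of the eye and ear (adjusted p = 0.0406 and 0.0284). foxi3b, a regulator of ionocyte progenitors, fell by 2.00 ± 0.27 (adjusted p = 0.0397) and gcm2 by 2.13 ± 0.19 (adjusted p = 0.00991). Of these only gcm2 passed under every alternative tried. Without control replicate 1 the adjusted p was 0.0517 for en2b, 0.114 for hmx4, 0.0864 for hmx1 and 0.196 for foxi3b, and these 4 calls were also lost without the variance trend. With normexp background correction en2b stood at -1.86 and hmx1 at -1.44, both past the threshold, and hmx4, at -1.44, and foxi3b, at -1.12, lost their calls, as they did without the filter on dim probes.

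gfi1aa, a zinc finger transcriptional repressor, fell by 2.95 ± 0.39 (adjusted p = 0.0378), acbd7 by 2.65 ± 0.26 (adjusted p = 0.0164) and uraha, an enzyme of urate breakdown, by 2.06 ± 0.24 (adjusted p = 0.0292). Without the variance trend the calls of gfi1aa (0.108), acbd7 (0.0722) and uraha (0.107) were lost, and without control replicate 1 those of gfi1aa (0.0609) and uraha (0.0592). gfi1aa also lost its call without the filter on dim probes (0.0683) and with normexp background correction, where it stood at -1.64 (0.0794). egr2a, a relative of the hindbrain gene egr2b, was not well above background in T1 embryos and was at least 3.37-fold lower there (adjusted p = 0.0301). With normexp background correction egr2a stood at -0.41 (adjusted p = 0.204), and its call was also lost without the filter on dim probes (0.0512), without the variance trend (0.0609) and without control replicate 1 (0.128). The 2 tested probes of hmx4, at -2.35 and -1.56, did not pass when adjusted over all probes.

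**Figure D2:**
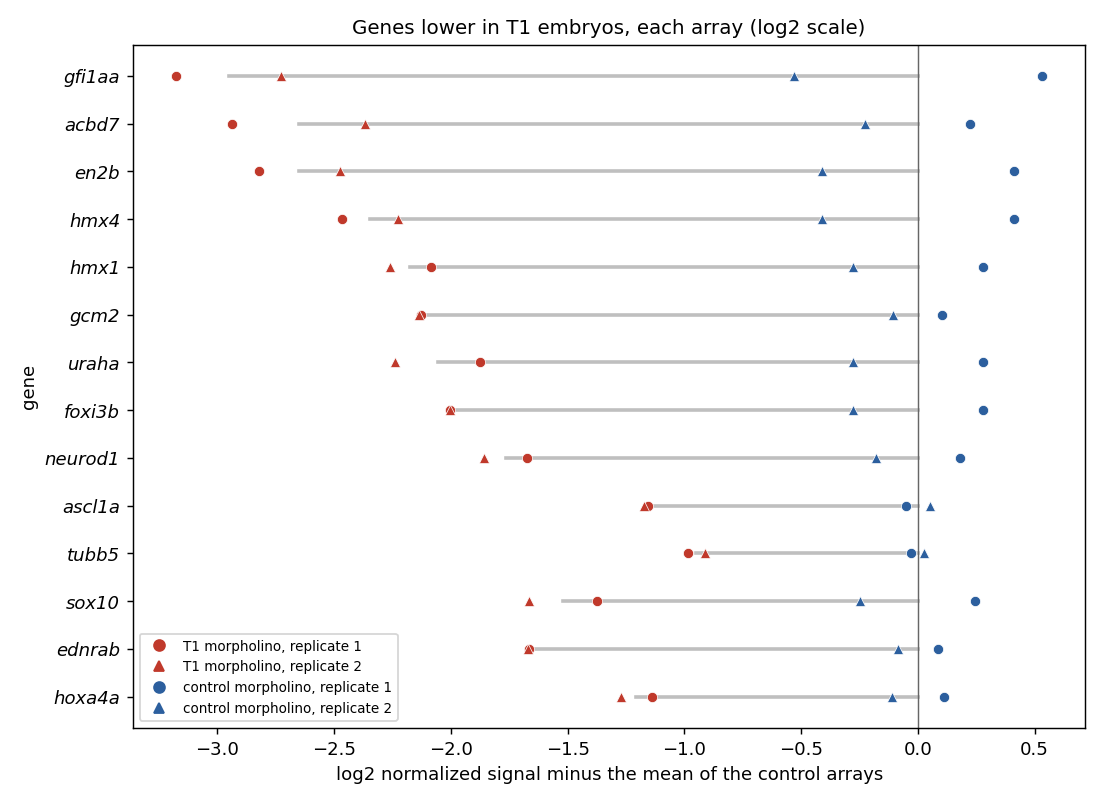
Each point is the log2 normalized signal of a gene on 1 array minus the mean of the control arrays, with red for T1 and blue for control embryos, circles for replicate 1, triangles for replicate 2 and a grey line to the T1 mean. Both T1 arrays lie below both control arrays for every gene drawn, from gfi1aa at -2.95 to tubb5 at -0.95.

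In the neuronal differentiation list 3 of 27 measured genes fell and none rose, and 24 were lower in T1 embryos whether or not they passed. The 3 were the proneural genes neurod1, at -1.77 ± 0.21 (adjusted p = 0.03), and ascl1a, at -1.17 ± 0.16 (adjusted p = 0.0451), and the beta-tubulin gene tubb5, at -0.95 ± 0.12 (adjusted p = 0.0321). Without control replicate 1 none of the 3 passed, with adjusted p = 0.128 for neurod1, 0.212 for ascl1a and 0.167 for tubb5, and without control replicate 2 only 1 list member passed. The call of ascl1a was lost in 7 of 14 alternatives, that of tubb5 in 5 and that of neurod1 in 2. Adjusted over the list alone, 8 were lower and 1 was higher. The median was -0.35 (camera adjusted p = 4.05e-07, adjusted p = 0.461 with an estimated correlation). In the neural plate and brain patterning list 2 of 48 genes fell, among them en2b, and 8 were lower and 1 higher adjusted over the list alone. Its median was -0.16 (camera adjusted p = 0.0308, adjusted p = 0.651 with an estimated correlation), and -0.09 without T1 replicate 1 and -0.07 without control replicate 2.

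Of 41 hox genes, the positional regulators of the trunk and hindbrain, hoxa4a fell, at -1.21 ± 0.16 (adjusted p = 0.0374), and none rose. The call of hoxa4a was lost in 5 of 14 alternatives, among them median scaling (0.0571), and without either control replicate no hox gene passed. Adjusted over the list alone, 7 were lower. The list median was -0.38, with 33 genes lower (camera adjusted p = 8.89e-07, adjusted p = 0.461 with an estimated correlation). In the neural crest list sox10, a transcription factor of crest cells, at -1.52 ± 0.21 (adjusted p = 0.0446), and ednrab, an endothelin receptor gene, at -1.67 ± 0.24 (adjusted p = 0.0472), fell among 18 genes. Adjusted over the list alone 4 were lower, and the list was not called (camera adjusted p = 0.444). The call of sox10 was lost in 4 of 14 alternatives, with adjusted p up to 0.143, and that of ednrab in 7, among them leaving out any 1 array, with adjusted p up to 0.304, and with normexp background correction ednrab stood at -0.69.

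Genes of earlier stages stood on the other side. In the list of gastrula-stage genes 33 of 41 were higher in T1 embryos, and foxi1, a forkhead gene of non-neural ectoderm, rose by 1.04 ± 0.15 (adjusted p = 0.0472). The call of foxi1 was lost in 9 of 14 alternatives, among them leaving out any 1 array, median scaling (adjusted p = 0.094) and no scaling (0.0886), with adjusted p up to 0.294, and its probe did not pass over all probes. Adjusted over the list alone, 11 were higher and 1 was lower. The median was 0.25 (camera adjusted p = 1.49e-05, adjusted p = 0.845 with an estimated correlation). ndr1, a Nodal ligand gene, stood at 1.73 ± 0.28 (adjusted p = 0.0664) and nanog at 1.03 ± 0.22 (adjusted p = 0.132), and neither passed. foxi1 was also the only gene past the threshold among 24 in the BMP target list, there too adjusted over the list alone (camera adjusted p = 0.444). In the list of epidermis, periderm and ionocyte genes foxi1 rose and foxi3b fell among 39, with 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.858).

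In the fit without a replicate block none of 47 muscle differentiation genes passed over all genes, and 10 were lower adjusted over the list alone. The list had a median of -0.25 and 33 genes lower (camera adjusted p = 0.000295, adjusted p = 0.461 with an estimated correlation). The myogenic factor genes myod1, at -0.01 ± 0.14 (adjusted p = 0.992), and myf5, at -0.16 ± 0.12 (adjusted p = 0.673), did not pass, nor did myog, at -1.32 ± 0.25 (adjusted p = 0.099). The slow myosin gene smyhc1 stood at -1.53 ± 0.24 (adjusted p = 0.0638). Of 75 ribosomal protein genes none passed under either adjustment, while 69 were lower, with a median of -0.11 (camera adjusted p = 0.00821, adjusted p = 0.906 with an estimated correlation). The ribosomal median was -0.03 without T1 replicate 2 and -0.19 without T1 replicate 1. The mean of the ribosomal list was below 0 under the 75th percentile, median, quantile and no scaling. In the cytoskeleton and cell adhesion list tubb5 fell among 40 genes, also when adjusted over the list alone (camera adjusted p = 0.455).

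**Figure D3:**
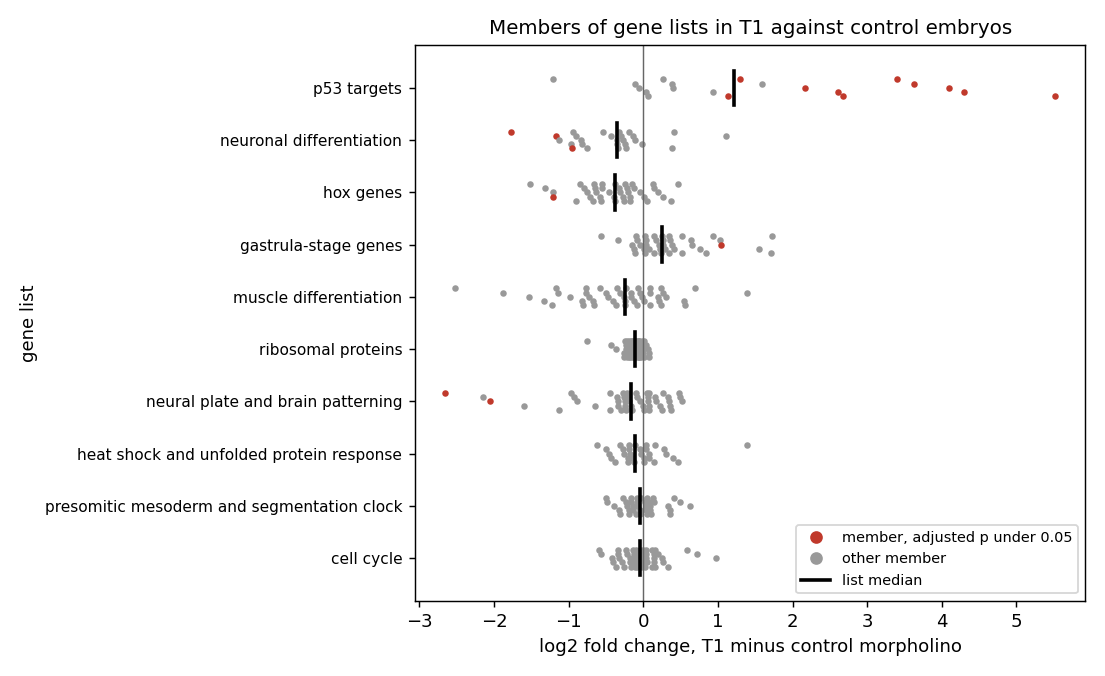
Each point is the log2 fold change of a list member, T1 minus control, in red where the adjusted p over all genes was under 0.05, and the black bar is the list median. The p53 target list has its median at 1.21, and the presomitic, cell cycle and heat shock lists have theirs at -0.04, -0.05 and -0.11.

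The other 19 lists had no member past the threshold and adjusted p from 0.0702 to 0.858. Among them were blood and endothelium, with a median of -0.20 over 34 genes (adjusted p = 0.0702), pronephros, -0.13 over 13 (adjusted p = 0.0702), Notch targets, -0.24 over 25 (adjusted p = 0.0859), the segmentation clock and presomitic mesoderm, -0.04 over 38 (adjusted p = 0.858), the cell cycle, -0.05 over 53 (adjusted p = 0.62), and the heat shock and unfolded protein response, -0.11 over 31 (adjusted p = 0.444). Tissue markers were among these lists too, with medians of 0.21 for hatching gland over 12 genes, -0.13 for the yolk syncytial layer over 25 and -0.08 for notochord over 19. The blood list was called without T1 replicate 1 (adjusted p = 0.031) and without control replicate 2 (0.00376), and its median was -0.02 without T1 replicate 2. The median of the yolk syncytial layer list was 0.13 without control replicate 1 and -0.31 without control replicate 2, where the list was called (adjusted p = 0.0439). Without control replicate 2 the median was -0.09 for Notch targets, -0.05 for pronephros and 0.08 for hatching gland. Without T1 replicate 2 it was 0.05 for the cell cycle and -0.03 for notochord. The presomitic median was 0.01 without T1 replicate 1, and the heat shock median was -0.06 without T1 replicate 1 and -0.05 without control replicate 1. The Hedgehog target list, over 18 genes, had a median of 0.03 and a mean of -0.01.

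In all, 99 of 13316 genes passed, 62 higher and 37 lower in T1 embryos, and 97 of them changed by at least 2-fold. At the level of probes 145 of 28641 passed, 101 higher and 44 lower. An unadjusted p under 0.05 was reached by 1668 genes and 3129 probes. Both T1 arrays lay beyond both control arrays for 43.7% of genes, against 33.3% by chance if the arrays were exchangeable. Replicate differences shared by the groups, with r = 0.55 across probes, go against that, so the chance share here is not known. Of the genes past the threshold 62.6% were higher, and 44.8% without scaling between arrays, where the median log2 fold change of all genes was -0.13 in place of -0.01. The gene count fell to 52 without control replicate 1, to 61 without the filter on dim probes and to 21 without the variance trend, and the probe count was 231 without T1 replicate 2. The call of the neural plate list ended with quantile normalization (adjusted p = 0.064) and without T1 replicate 1 (0.145) or control replicate 2 (0.198), and that of the ribosomal list with quantile normalization (0.064) and without T1 replicate 2 (0.487) or control replicate 1 (0.322).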

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

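The sign of each of the 32 named genes that passed, of 35 tested, and of the mean of each of the 7 called lists held under every alternative that gave it a value. For the genes this was largely fixed beforehand. Each had both T1 arrays beyond both control arrays, so leaving out an array could not reverse its sign. The filter, block and eBayes settings left its fold unchanged. Over 487 comparisons of single genes with an alternative, 412 kept their side of the threshold, 74 lost it, 1 gained it and 0 reversed. Few named genes could gain a call, as most had passed. Of 112 comparisons of called lists 92 kept the call and 20 lost it. The list tests do not use eBayes, so those without the trend or with robust estimation repeat the reported list results. Without the filter on dim probes 78 probes and 61 genes passed, all among those reported, with more probes tested. Without the variance trend 37 probes, 21 genes and 12 named genes passed, against 145, 99 and 32, with 20 of the 21 genes among the 99, and the cause was not tested. At an adjusted p under 0.10 the counts were 291 probes and 223 genes. Leaving out 1 array gave 110 to 231 probes, 52 to 127 genes, 14 to 29 named genes and 6 to 8 lists, with fewer samples. The lowest gene and named-gene counts came without control replicate 1, where 41 of the 99 genes remained, and the highest probe count without T1 replicate 2. With an estimated correlation 0 of 32 lists were called by camera, with 2 at an unadjusted p under 0.05, and fry called 1, the p53 targets. The few degrees of freedom of that camera setting weigh on this count. For the muscle list the estimated correlation was 0.0115, near the preset 0.01, yet the unadjusted camera p went from 4.61e-05 to 0.0577. No beta-defensin probe passed under any alternative, since none was tested except without the filter, where the lowest adjusted p was 0.801. The replicate numbers are shared by the groups, but no label says that a number marks a shared clutch. Replicate 1 minus replicate 2 correlated between the groups with r = 0.55 across 28641 probes, which are not independent. With the replicate number as a block 3506 probes and 1932 genes passed, all 145 and 99 among them, and 6 lists were called, without the neural plate list (adjusted p = 0.0858). Of all genes 936 were then higher and 996 lower. Members past the threshold numbered 17 lower and 3 higher in the muscle list, 17 and 1 in the hox list and 10 and 3 in the neuronal list. In the gastrula-stage list 13 were higher and 1 lower, and in the apoptosis machinery list 3 and 1. In that fit myog also passed (adjusted p = 0.000125). Of the named genes only myod1, myf5 and myog could gain a call, as the others had passed without the block. Dim genes are limited by the background, since 64.3% to 67.5% of the probes of an array were well above it. The planned use of the authors' normalized table was not run.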

Other observations

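The tests of scaling, of the number of morpholinos and of probe trends, and the 3 added gene lists, were chosen only after the results they bear on were seen. Further genes past the threshold, chosen after their values were seen, extend both directions. Among those higher in T1 embryos were exo5, a DNA repair exonuclease, 6.99-fold, parp3, of the poly(ADP-ribose) polymerase family, 3.32-fold, the cell cycle inhibitor gene cdkn1ba, 2.23-fold, gadd45bb, 3.16-fold, and gnrh2, a gonadotropin-releasing hormone gene, 5.57-fold. Among those lower were the neural transcription factor genes atoh1b, 3.72-fold, bhlhe22, 3.29-fold, tlx3b, 2.88-fold, and lhx9, 2.62-fold, and the eye gene mab21l2, 3.35-fold. The 2 tested probes of tlx3b, at -1.52 and -0.44 on the log2 scale, did not pass when adjusted over all probes. Neither did the 2 of lhx9, at -1.99 and -1.39.

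The blood and endothelium list was not called (adjusted p = 0.0702), with 22 of 34 members lower and 12 higher and a median of -0.02 without T1 replicate 2. Of its members, chosen after their values were seen and none past the threshold, gata1a, the erythroid master regulator, stood at -3.45 ± 0.55 (adjusted p = 0.0638) and was well above background on 1 of the 2 T1 arrays, tal1 at -1.39 ± 0.23 (adjusted p = 0.0736) and lmo2 at -1.31 ± 0.31 (adjusted p = 0.166). The globin genes hbae3, at -0.30 ± 0.24, and hbbe2, at 0.19 ± 0.29, were closer to 0. In a list of forebrain and eye genes, without the genes that prompted it, none of 24 genes passed over all genes, 8 were lower adjusted over the list alone, and 14 also stood in the neural plate list. The median was -0.27 (camera p = 6.77e-06, and p = 0.0532 with an estimated correlation). Its lowest members were the retinal homeobox gene rx2, at -2.15 ± 0.36 (adjusted p = 0.0749), and fezf1, at -2.14 ± 0.34 (adjusted p = 0.0661).

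Of 20 p53 targets 17 were higher in T1 embryos and 3 lower, and 10 rose past the threshold. With an estimated correlation, where camera has little power on 4 arrays, the list had an adjusted p = 0.461. The choice among the 4 scalings tried is argued against, since the lowest median of the list over them was 1.09. Median scaling and no scaling shift every gene alike. The median log2 fold change of all genes was -0.06 and -0.13 under these, so the list could not have fallen far. A general stress response that raises the heat shock and oxidative stress lists as a whole is argued against as well. The heat shock list had a median of -0.11 and the oxidative stress list one of 0.0263, with an upper bound of 0.13 over genes. A response in part of these genes or in others is not excluded. Without regard to direction fry called both lists (adjusted p = 0.00982 and 0.0203), as it did 19 of 32 lists. Leaving out 1 array at a time, the oxidative stress median reached 0.14, without T1 replicate 2, and that of the heat shock list stayed below 0. What also stays open is whether loss of defbl1 or another effect of the oligonucleotide raised the p53 targets. These cannot be told apart, since 1 morpholino against defbl1 was on the arrays. The defbl1 probe was not well above background on any array, control arrays included, so the arrays do not show whether its transcript was present. In addition, p53 activation is a known effect of some morpholinos whatever their target.

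The added list of forebrain and eye genes had 19 of 24 members lower in T1 embryos and 5 higher, none past the threshold over all genes, so this pattern is itself a hypothesis. Slower development may account for part of this, as the muscle differentiation list had a median of -0.25 and the neuronal list -0.35 while the gastrula-stage list stood at 0.25. The presomitic list, at -0.04, and myod1, at -0.01, stood near 0, and no staging of the frozen embryos was analysed here. Loss of neural tissue as a whole remains open. The pan-neural list had a median of -0.20 and the midbrain and hindbrain list one of -0.17, against -0.27 for the forebrain and eye list. By their medians these lists met the mark set for this cause. That mark compares lists added after the data were seen, so it was not fixed before the data. The midbrain and hindbrain list also kept 1 gene past the threshold, while the forebrain and eye list left out the genes that prompted it. Their intervals, from -0.29 to 0.06 and from -0.38 to 0.07, also reached above 0.

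Replicate 1 and replicate 2 differed alike in both groups. Smooth trends on probe GC content, signal and position on the array are argued against, since the correlation of the differences was 0.55 after their removal. Different stages of the collections could contribute and stay open. The gastrula-stage list was lower in replicate 1 by 0.17 in T1 and 0.13 in control embryos. The muscle list shifted by 0.0316 and 0.0372, under the mark set in advance against this cause. Its intervals, from -0.0819 to 0.16 and from -0.00548 to 0.21, included no shift as well as larger ones. The yolk syncytial layer list was higher in replicate 1 by 0.31 in T1 and 0.50 in control embryos. No label names a clutch or day, so neither was tested here.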
